A study of Homo sapiens with 6 samples.

How the data were processed

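RNA-seq was done on THP-1 cells, a human monocytic leukaemia line, in 3 cultures labelled SPI1 knockdown and 3 labelled WT. SPI1 encodes PU.1, an ETS family transcription factor of myeloid and B cells. The labels describe total RNA isolated with TRIzol and paired reads of 150 bases from a DNBSEQ instrument, and the series design names siSPI1, a small interfering RNA (siRNA) against SPI1. The labels do not say whether the WT cells received a control siRNA, so an effect of the knockdown and an effect of the transfection share the same contrast.

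The deposited tables hold 1 library each, with 60624 genes per table. Per the file headers they are RSEM gene tables, and the deposited expected count is the estimated number of read pairs per gene, with shared reads split between genes and no normalization. The deposited TPM values are shares of a library's transcripts, scaled to the same total in every library and corrected by the authors for effective transcript length. The deposited FPKM values are fragments per kilobase of effective length, scaled to the library's fragments. The deposited length and effective length of each gene are in bases. Per the submitters' processing notes, Trim Galore 0.6.4, STAR 2.7.3, featureCounts of Subread 2.0.0, RSEM 1.3.2 and DESeq2 1.36.0 were used with genome build GRCh38, and the notes as available name no role for each tool. The strand setting and the annotation release were not given in the sources used here.

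Symbols came from a name table that covers 60370 of the gene identifiers, and positions, gene types and exons came from GENCODE 29 (GRCh38), which holds 58437 of them. At most 0.103% of a library's counts lay on identifiers absent from GENCODE 29. Over all 60624 genes of a library, those without reads included, between 9.33% and 10.3% of the expected counts were not whole numbers. The share among genes with reads is higher. Expected counts were rounded to whole numbers for the tests, and a gene with counts that are not whole in each of the 6 libraries was taken as a gene whose reads were shared with other genes.

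The comparison of 3 SPI1 knockdown libraries with 3 WT libraries used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, genes kept by filterByExpr (16045 genes), and Benjamini-Hochberg adjusted p under 0.05 as the threshold. The test is two-sided. Levels are TMM-normalised CPM, counts scaled to a common library total, with the standard deviation over the 3 libraries of a group, and the standard error of a log2 fold change is its size divided by the square root of F. With 3 libraries against 3, an exact permutation test of a single gene cannot give a p below 0.1, so tests across all genes were used. The p-values measure the spread among cultures that the design text calls biological replicates.

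Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over 30 lists of at least 5 tested genes. Camera with an estimated correlation, fry, and cameraPR on the edgeR statistics were run beside it. The lists cover PU.1 targets, myeloid and immune functions, stress, growth and metabolism, silencing of transposable elements, and markers of other cell types. Some genes are in more than 1 list, and SPI1 itself is in none.

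The genes named in the text follow a rule. They are SPI1, then the 8 largest rises and the 8 largest falls among protein-coding genes past the threshold with a mean of at least 5 CPM and no overlap between the groups. From each list the rule adds up to 4 called members with the smallest adjusted p, and up to 2 members that were not called, taken by highest mean CPM. It names 186 genes, of which 28 have counts that are not whole in all 6 libraries and 43 have exons that overlap those of another tested gene. Genes outside it are given as chosen after their values were seen. The test, the 30 lists, the rule and the alternatives were fixed before the data were examined, except where the text says otherwise.

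The alternatives changed 1 choice each, except that DESeq2 brings its own size factors and filter and that limma-trend on TPM changes the test, the scaling and the correction for length together. They were DESeq2 1.42.0, limma-voom, RLE and upper-quartile normalization, no filter on low counts, a filter of at least 1 CPM in 3 libraries, a block for the replicate number, limma-trend on log2 TPM with a pseudocount of 1 or 0.1, protein-coding genes alone, adjusted p under 0.01, an absolute log2 fold change above 1, and each library left out in turn. Removal of each library's trend with GC content and transcript length was added later. All 10 splits of the 6 libraries into 3 and 3 were also tested. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

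The procedure was tested on simulated data with this number of libraries. In them 50 genes were changed at each of 4 sizes, and a list of 30 more was raised 1.25-fold. The procedure recovered 60% of genes changed 1.25-fold, 88% of those changed 1.5-fold, 92% of those changed 2-fold and 100% of those changed 4-fold. It called 16 unchanged genes among 15844 tested. With so few changed genes the adjusted threshold is stricter than in the real comparison, whose recovery these shares do not give. FPKM values were not tested, since they are a rescaling of the same counts. Reads derived from transposable elements were not analysed, since the tables hold genes only, and the siRNA sequence was not given.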

Results

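Gene expression was measured in 6 THP-1 libraries, 3 from cells with SPI1 knockdown and 3 from WT cells. The knockdown libraries held 20271154, 20501985 and 20172935 expected counts, in replicates 1 to 3, and the WT libraries 20041462, 20349882 and 20481289. Between 23024 and 23684 genes had at least 1 expected count in a library. Protein-coding genes took between 96.8% and 97.1% of the counts and mitochondrially encoded genes between 4.87% and 5.15%. The series title places the experiment in a study of how transposable elements contribute to gene regulation in immune cells, and the comparison asks which transcripts differ when SPI1 is reduced.

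SPI1 (ENSG00000066336, GRCh38 chromosome 11, 47354860 to 47378576, minus strand) fell to 37.5% of its WT level, from 182 ± 18.7 CPM to 68.3 ± 1.35 CPM (SD, n = 3 each). Its log2 fold change was -1.41 (SE 0.06, edgeR adjusted p = 1.72e-11). CSF1R, the receptor for macrophage colony-stimulating factor and a known PU.1 target, fell from 115 ± 8.45 to 28.8 ± 0.91 CPM. All 45 tested interferon-stimulated genes fell, among them OAS3, a sensor of double-stranded RNA, from 688 ± 21.2 to 215 ± 13.5 CPM. CHI3L1, a secreted chitinase-like glycoprotein, rose from 1143 ± 64.9 to 2370 ± 69.6 CPM.

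**Figure D1:**
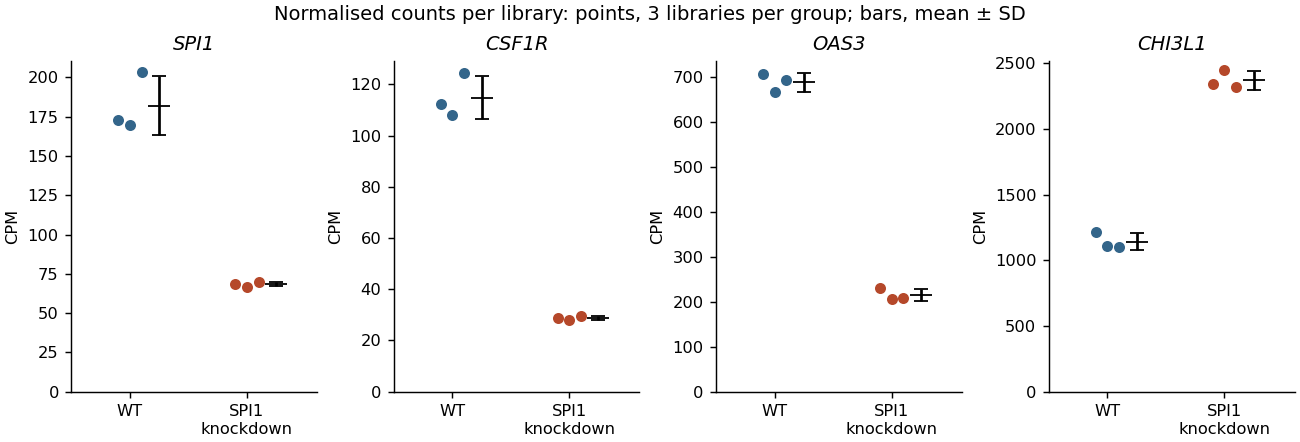
TMM-normalised counts (CPM) of SPI1, CSF1R, OAS3 and CHI3L1 in each library, with points for the 3 libraries of each group and bars for the mean ± SD. SPI1 lay between 66.8 and 69.5 CPM in the knockdown libraries and between 170 and 204 CPM in the WT libraries, and the groups did not overlap for any of the 4 genes.

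Of 16045 tested genes, 6957 (43.4%) changed, 3377 higher and 3580 lower in the knockdown. Most changes were small, with a median absolute log2 fold change of 0.42 and 4624 of the called genes (66.5%) under 1.5-fold. More than 2-fold changes were found for 494 higher and 508 lower genes. Of protein-coding genes 6257 of 13180 changed, of long non-coding genes 479 of 1856, and of pseudogenes 157 of 641. The groups did not overlap for 8356 genes (52.1%), against 10% given by chance for 3 against 3. The share of called genes that were higher was 48.5%, 48.1% with RLE factors and 54.8% with upper-quartile factors. Upper-quartile factors moved the log2 fold change of a gene by a median of 0.032. Limma-trend on TPM changes the test, the scaling and the correction for length together, and is called the TPM fits below. There the share was 66.8% with a pseudocount of 1 and 66.9% with 0.1. The log2 fold change of a gene lay higher there by a median of 0.098 and 0.104.

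Among protein-coding genes with a mean of at least 5 CPM, the largest rise was that of CAMKV (ENSG00000164076, chromosome 3, 49857988 to 49870222), a kinase-like vesicle protein of neurons, from 1.47 ± 0.223 to 16.5 ± 0.34 CPM (log2 fold change 3.48, SE 0.13, edgeR adjusted p = 1.21e-12). MTSS2, which binds actin and membranes, rose from 17.8 ± 2.73 to 167 ± 5.54 CPM (log2 fold change 3.23). CTTN, the actin-binding protein cortactin, rose from 4.65 ± 0.474 to 41.5 ± 3.55 CPM. The potassium channel gene KCNH2 had a log2 fold change of 2.68, the carbohydrate-response transcription factor MLXIPL (ChREBP) 2.64, the procollagen proteinase enhancer PCOLCE2 2.52, the autophagy regulator TP53INP2 2.47 and the myotonic dystrophy kinase DMPK 2.35.

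Among protein-coding genes with a mean of at least 5 CPM, the largest fall was that of CD209 (ENSG00000090659, chromosome 19, 7739994 to 7747564), the C-type lectin DC-SIGN of dendritic cells and macrophages, from 44.8 ± 4.63 to 7.44 ± 0.209 CPM (log2 fold change -2.59, SE 0.09, edgeR adjusted p = 5.16e-13). MPEG1, which encodes the pore-forming macrophage protein perforin-2, fell from 59.4 ± 9.85 to 10.5 ± 0.729 CPM. ZNF366, which encodes the dendritic cell transcript DC-SCRIPT, had a log2 fold change of -2.44 and DCANP1, another dendritic cell gene, -2.34. The sialyltransferase ST6GALNAC3 had -2.55, the adaptor STAP1 -2.52, the homeobox gene HESX1 -2.32 and FGD2, an exchange factor for CDC42, -2.24. Of the exon bases of DCANP1, 99.9% overlapped TIFAB on the same strand, and 64% of those of MTSS2 overlapped a gene of 3.88 CPM on the opposite strand.

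**Figure D2:**
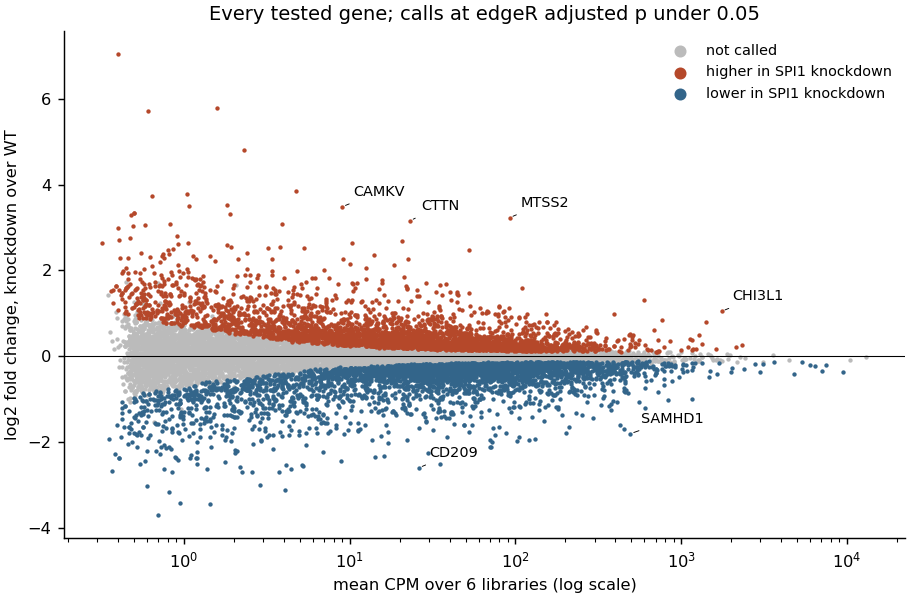
Mean CPM over 6 libraries (log axis) against log2 fold change, knockdown over WT, for the 16045 tested genes, with genes higher (3377) and lower (3580) at edgeR adjusted p under 0.05 in colour. Labelled genes include CAMKV at 3.48, CD209 at -2.59 and CHI3L1 at 1.05. The share of higher genes is 48.5% here and 66.8% in the TPM fits with a pseudocount of 1.

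Known PU.1 target genes were mostly lower. Of 35 tested, 29 fell and 1 rose, with the same counts adjusted over the list alone, and the median log2 fold change was -0.63 (camera adjusted p = 4.64e-12, adjusted p = 0.0586 with an estimated correlation). In the TPM fits with a pseudocount of 1 and 0.1, 22 were lower, 1 and 2 were higher, and the median was -0.43 and -0.47. Besides CSF1R, the high-affinity IgG receptor FCGR1A (log2 fold change -1.49) and lysozyme LYZ (-1.36) fell. LYZ went from 365 ± 15.2 to 142 ± 5.07 CPM. Neutrophil elastase ELANE (log2 fold change 0.08, adjusted p = 0.392) and the integrin ITGAM (-0.01, adjusted p = 0.918) were not called. CD14, the lipopolysaccharide co-receptor, was the member that rose, from 1.57 to 3.08 CPM (log2 fold change 0.97), and was chosen after its values were seen. Without WT replicate 3 the number of higher members was 3, and ELANE was called with a log2 fold change of 0.21.

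Myeloid surface receptors fell together, 40 of 46 tested and 2 rising, with the same counts adjusted over the list alone (median log2 fold change -0.98, camera adjusted p = 1.09e-15, adjusted p = 0.0586 with an estimated correlation). The median was -0.58 and -0.84 in the TPM fits with a pseudocount of 1 and 0.1, with 33 lower. The inhibitory receptor LILRB4 went from 277 ± 14.6 to 107 ± 0.154 CPM and the chemokine receptor CCR1 from 97 ± 4.58 to 41.1 ± 1.69 CPM. Inflammatory cytokines and chemokines fell in 17 of 25 tested genes with 0 rising, or 17 and 1 adjusted over the list alone (median -0.86, camera adjusted p = 9.92e-06, adjusted p = 0.266 with an estimated correlation). The median was -0.53 and -0.63 in the TPM fits, with 15 lower. TNF went from 42.9 ± 6.35 to 14.9 ± 0.766 CPM, the interleukin-1 receptor antagonist IL1RN from 42.4 ± 2.32 to 15 ± 1.42 CPM, and the B cell activating factor TNFSF13B had a log2 fold change of -1.17. IL18 averaged 12.9 CPM in both groups (adjusted p = 0.987).

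Of 9 NADPH oxidase genes, whose products make superoxide in phagocytes, 7 fell and 0 rose, also adjusted over the list alone (median -0.35, camera adjusted p = 5.78e-04, adjusted p = 0.266 with an estimated correlation). Of these genes 6 were lower in the TPM fits, and 1 was higher with a pseudocount of 0.1 and without WT replicate 3. CYBB, the catalytic subunit, went from 15 ± 1.03 to 4.58 ± 0.126 CPM, and the proton channel HVCN1 had a log2 fold change of -1.12. RAC2 (-0.07, adjusted p = 0.298) was not called. In the Toll-like receptor and inflammasome pathway 19 of 33 fell and 5 rose, or 20 and 5 adjusted over the list alone (median -0.30, camera adjusted p = 3.84e-04, adjusted p = 0.0923 with an estimated correlation). In the TPM fits with a pseudocount of 1 and 0.1 the number that fell was 11 and 12 and the median -0.15 and -0.17. The adaptor MYD88 had a log2 fold change of -0.87, CASP1 -0.76, NLRP12 -1.77 and NAIP -1.18. Granule proteins went both ways, 6 of 19 higher and 8 lower, or 6 and 10 adjusted over the list alone (camera adjusted p = 0.187), with the protease inhibitor SERPINB1 at 1.13, S100A9 at -1.26 and PLAC8 at -0.79.

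Genes of antigen presentation by MHC class II fell in 11 of 14 with 0 rising, also adjusted over the list alone (median -0.70, camera adjusted p = 1.98e-05, adjusted p = 0.188 with an estimated correlation). The median was -0.46 and -0.53 in the TPM fits. The invariant chain CD74 went from 297 ± 14.6 to 172 ± 4.25 CPM and HLA-DRA from 19.1 ± 1.86 to 9.1 ± 0.609 CPM. For MHC class I 13 of 19 fell and 1 rose, also adjusted over the list alone (median -0.36, camera adjusted p = 1.29e-04, adjusted p = 0.404 with an estimated correlation). The immunoproteasome subunit PSMB9 had a log2 fold change of -0.90, the peptide transporter TAP2 -0.59 (32.3% of its exon bases overlap a gene of 14.4 CPM on the same strand) and HLA-E -0.54. The member that rose was the chaperone CALR (0.51), chosen after its values were seen. Lysosome genes fell in 28 of 42 with 8 rising, or 28 and 9 adjusted over the list alone (median -0.22, camera adjusted p = 0.00113, adjusted p = 0.319 with an estimated correlation). In the TPM fits the number that fell was 15 and 16 and the median -0.10 with either pseudocount. Cathepsin S (CTSS, -0.62) and the galactosidase GLA (-0.85) fell, and cathepsin L (CTSL) rose from 113 ± 1.53 to 182 ± 10.9 CPM.

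Macrophage differentiation genes moved in both directions, 8 of 25 higher and 15 lower, or 9 and 15 adjusted over the list alone (camera adjusted p = 0.221). In the TPM fits 7 were higher and 11 lower with either pseudocount. The oxysterol receptor NR1H3 (LXR alpha) rose from 11.4 ± 1.51 to 27.6 ± 0.634 CPM, while the lipid receptor TREM2 went from 22.8 ± 1.81 to 8.87 ± 0.887 CPM. Of 46 myeloid transcription factors 24 fell and 8 rose, or 24 and 9 adjusted over the list alone (median -0.22, camera adjusted p = 0.00296, adjusted p = 0.199 with an estimated correlation). In the TPM fits 16 were lower and 10 higher, with medians of -0.09 and -0.12. FOS (log2 fold change -1.15), KLF4 (-1.24), TFEC (-1.18) and IKZF1 (-0.80) fell. Among the members that rose, IRF8 had a log2 fold change of 0.36, CEBPA 0.38, MYC 0.29 and RUNX1 0.22, and these were chosen after their values were seen. Of 20 ETS family factors 9 fell and 2 rose, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.0758). ETS1 rose from 50.1 ± 1.95 to 99.7 ± 4.36 CPM, and ELF4 had a log2 fold change of -0.67.

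Interferon-stimulated genes fell in all 45 tested members, also adjusted over the list alone, 25 of them by more than 2-fold (median -1.06, camera adjusted p = 6.55e-25, adjusted p = 0.199 with an estimated correlation). CMPK2, a mitochondrial nucleotide kinase, went from 192 ± 8.52 to 49.6 ± 4.89 CPM, IFIT3 from 165 ± 4.36 to 44.7 ± 3.98 CPM, and the antiviral GTPase MX2 from 332 ± 6.12 to 134 ± 6.35 CPM. Genes of the unfolded protein and integrated stress responses fell in 26 of 32 with 3 rising, also adjusted over the list alone (median -0.38, camera adjusted p = 1.33e-07, adjusted p = 0.266 with an estimated correlation). In the TPM fits 20 were lower and 3 higher, with medians of -0.26 and -0.28. The members with the smallest adjusted p were amino acid and one-carbon enzymes that ATF4 is known to induce. The serine synthesis enzyme PSAT1 went from 532 ± 37.2 to 226 ± 3.07 CPM, PHGDH had a log2 fold change of -0.84, the asparagine synthetase ASNS -1.08 (44.6% of its exon bases overlap a gene of 13.5 CPM on the same strand) and MTHFD2 -0.77. XBP1 (-0.10, adjusted p = 0.114) was not called in the edgeR test on all libraries, but was without WT replicate 1, with a log2 fold change of -0.15.

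Cell cycle and DNA replication genes fell in 34 of 53 with 1 rising, or 35 and 1 adjusted over the list alone (median -0.19, camera adjusted p = 2.96e-06, adjusted p = 0.0586 with an estimated correlation). CDK1 went from 149 ± 8.25 to 99.9 ± 5.55 CPM and KIF23 had a log2 fold change of -0.56, while the replication factor MCM4 (0.01, adjusted p = 0.86) was not called. In the TPM fits 11 members were lower with either pseudocount, and the median was -0.06. Genes of the p53 pathway and apoptosis went both ways, 8 of 32 higher and 11 lower, or 9 and 11 adjusted over the list alone (camera adjusted p = 0.64), and in the TPM fits 11 were higher and 5 lower with either pseudocount. TP53INP1 rose from 2.61 ± 0.247 to 9.25 ± 0.497 CPM and PMAIP1 (NOXA) had a log2 fold change of -0.78. Of 17 heat shock proteins 5 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.273), with HSPA4L at 1.08. The number that rose was 9 in the TPM fits with either pseudocount and 3 without knockdown replicate 1. Of 24 immediate early genes 9 fell and 4 rose, or 11 and 5 adjusted over the list alone (camera adjusted p = 0.153), with EGR1 at -1.22 and the phosphatase DUSP4 at 1.68, and 4 were lower in the TPM fits with either pseudocount.

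The lists of cholesterol synthesis, glycolysis and oxidative phosphorylation were not called. Of 23 cholesterol synthesis genes 9 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.0758, and 0.0198 without WT replicate 2), with HMGCS1 at -0.47. In the TPM fits 4 of them were lower and 2 higher, and 9 were lower with 1 higher with upper-quartile factors and 2 higher without WT replicate 3, where the median went from -0.065 to -0.013. Of 23 glycolysis genes 6 rose and 7 fell, or 6 and 8 adjusted over the list alone, and the median of 0.05 and the mean of -0.12 differed in sign (camera adjusted p = 0.749, direction lower). The glucose transporter SLC2A3 had a log2 fold change of -1.74, the hexokinase HK2 -0.84 and the lactate transporter SLC16A3 0.51. The number that rose was 3 in each fit without knockdown replicate 1, 2 or 3 or WT replicate 1. The median was 0.12 in the TPM fits, 0.08 with upper-quartile factors, 0.001 without knockdown replicate 2 and -0.01 without WT replicate 2.

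Of 42 oxidative phosphorylation genes 3 rose and 7 fell, or 2 and 4 adjusted over the list alone (camera adjusted p = 0.26), and the median turned from -0.08 to 0.02 in the TPM fits, where 7 were higher and 0 lower. The complex I subunit NDUFS3 rose from 78.4 ± 8.4 to 109 ± 5.79 CPM. The number lower was 3 without knockdown replicate 1, 2 without knockdown replicate 3 (median -0.04), 4 without WT replicate 1, 11 without WT replicate 2 and 4 with upper-quartile normalization, and the number higher was 5 without WT replicate 3. Of 54 cytosolic ribosomal proteins 11 fell and 0 rose, or 3 and 0 adjusted over the list alone (median -0.08, camera adjusted p = 0.0346, adjusted p = 0.762 with an estimated correlation), and the median turned to 0.02 in the TPM fits, where 3 members (4 with a pseudocount of 0.1) were higher and 1 lower. It was -0.05 with upper-quartile factors and without knockdown replicate 3. That call was lost without knockdown replicate 1 (adjusted p = 0.115), knockdown replicate 3 (0.208) or WT replicate 3 (0.217), where 4, 3 and 6 members were lower, against 7 without WT replicate 1, 18 without WT replicate 2 and 6, with 1 higher, with upper-quartile normalization. Of 13 mitochondrially encoded genes 5 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.0758, and 0.0243 with 8 lower without WT replicate 2), with MT-ND6 at -0.50 and MT-CO1 (-0.08, adjusted p = 0.103) not called. All 5 of these calls were lost with limma-trend in the TPM fits.

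Genes that act against transposable elements fell in 11 of 37 and rose in 5, or 12 and 5 adjusted over the list alone (camera adjusted p = 0.187, and 0.0332 with cameraPR), and the median of -0.06 was -0.025 with upper-quartile factors and turned to 0.04 in the TPM fits, where 7 were lower and 7 higher (6 with a pseudocount of 0.1). SAMHD1, a dNTP hydrolase that restricts retroviruses and retrotransposons, went from 766 ± 17.1 to 221 ± 10.9 CPM (log2 fold change -1.80, edgeR adjusted p = 4.9e-14). The cytidine deaminase APOBEC3G had a log2 fold change of -0.72, the KRAB zinc finger gene ZNF93, which binds LINE-1 elements, -0.64, and the heterochromatin protein gene CBX3 -0.48. The co-repressor TRIM28 (0.13, adjusted p = 0.082) was not called on all libraries and was called at 0.21 without WT replicate 3. Without knockdown replicate 1 the number that rose was 3. Of 5 tested replication-dependent histone genes 4 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.187), at levels of a few CPM such as H2AC6 at 3.42 ± 0.647 against 1.4 ± 0.589 CPM.

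The lists of markers of other cell types were not called. Of 8 tested T and NK cell markers 1 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.749), and granulysin GNLY rose from 0.169 ± 0.078 to 1.49 ± 0.327 CPM. In the TPM fits 1 of them was lower with a pseudocount of 1 and 0 with 0.1, while GNLY was called with both. Of 7 B cell markers 1 rose and 4 fell, or 2 and 4 adjusted over the list alone (camera adjusted p = 0.317). PAX5, the B cell identity factor, went from 21.7 ± 1.59 to 5.62 ± 0.351 CPM, and EBF1 rose from 0.203 ± 0.0501 to 1.04 ± 0.122 CPM. Of 8 erythroid and megakaryocyte markers 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.49), with NFE2 at 1.16, TFRC at 0.54 and CA2 at -0.41. The median of that list was -0.02 and turned to 0.01 with upper-quartile normalization and to 0.09 and 0.12 in the TPM fits, and with 1 library left out it lay between -0.10 (without WT replicate 3) and 0.06 (without knockdown replicate 2). Of 14 stem and progenitor markers 4 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.849), with CDK6 at 0.53, GATA2 at 0.77, FLT3 at -0.46 and HOXA9 at -0.40. Of 10 fibroblast, epithelial and endothelial markers 3 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.735), with PECAM1, which monocytes also express, at -0.49. The median of that list was -0.07 and its mean 0.13, and the median turned to 0.12 and 0.35 in the TPM fits with a pseudocount of 1 (1 higher) and 0.1. With 1 library left out it lay between -0.20 (without knockdown replicate 1) and 0.13 (without knockdown replicate 2).

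**Figure D3:**
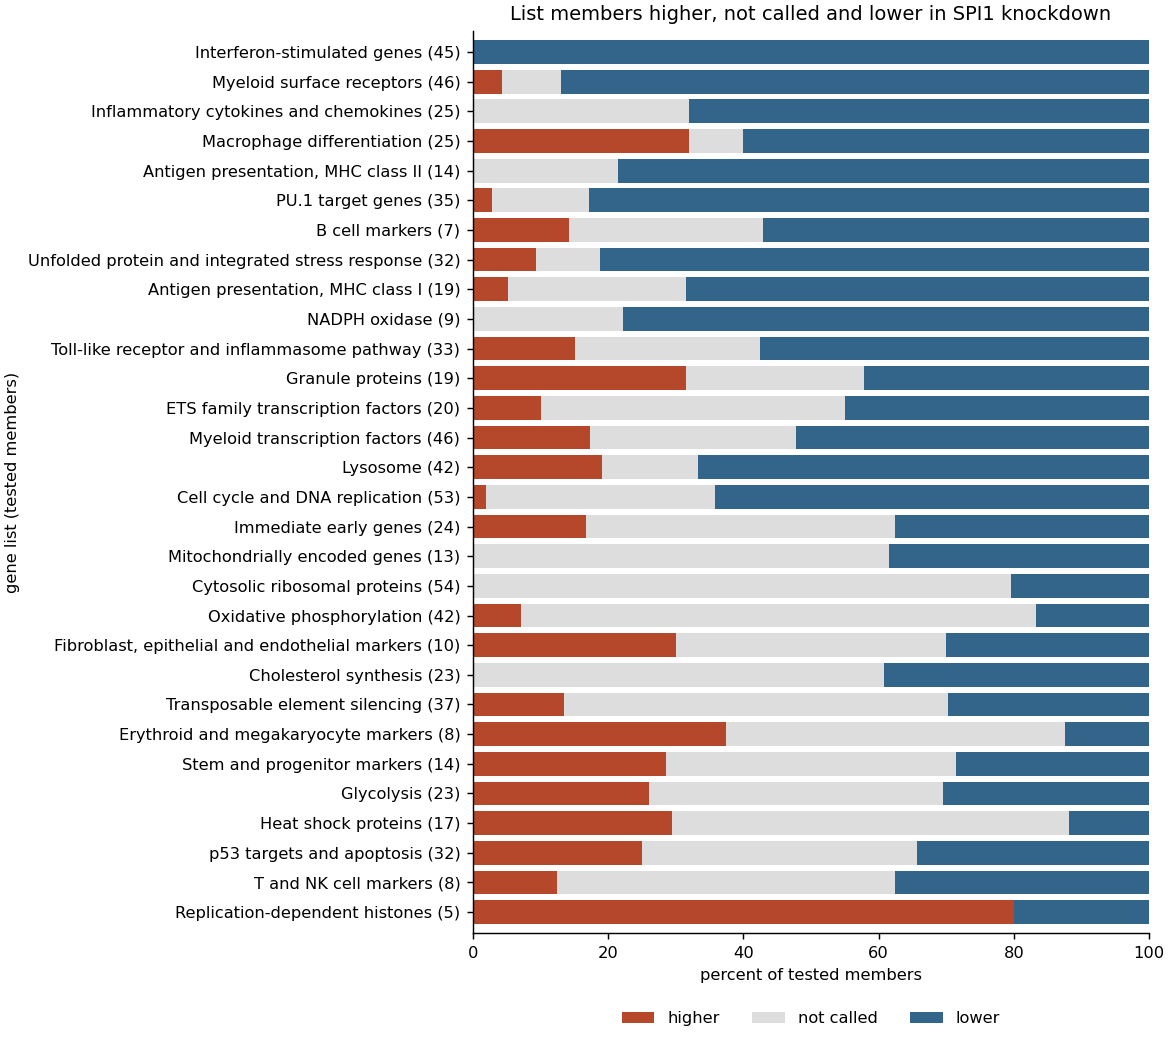
Percent of tested members of each of the 30 gene lists that were higher, not called or lower in the knockdown at edgeR adjusted p under 0.05, with the number of tested members in brackets. All 45 interferon-stimulated genes and 40 of 46 myeloid surface receptors were lower, while the medians of the oxidative phosphorylation, ribosomal protein, transposable element silencing, erythroid and fibroblast lists turn sign in the TPM fits.

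Every called gene named here passed edgeR at an adjusted p under 0.05 with all 3 knockdown libraries on the same side of all 3 WT libraries. Camera with the preset correlation called 13 of the 30 lists, all lower, and with an estimated correlation 0 (7 at an unadjusted p under 0.05), while fry called 24 and cameraPR 13. The cultures differed by replicate spread that was small beside the contrast, with correlations of log2 CPM between 0.992 and 0.994 within groups and between 0.975 and 0.979 across groups, and a biological coefficient of variation of 5.08%. Reads were partly shared with other genes for MTSS2, ZNF366, DCANP1, FCGR1A, LYZ, NAIP, TAP2, GLA, ASNS, MTHFD2, HSPA4L, NDUFS3, SAMHD1 and CEBPA, whose expected counts were not whole in any library. Since the labels do not say how the WT cells were treated, the contrast holds the knockdown and any effect of siRNA transfection together.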

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

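Removal of the trend with GC content and transcript length was chosen only after the results were seen, and the other alternatives were planned. The 6957 changed genes became 5609 with DESeq2 (5552 shared), 6931 with limma-voom, 6960 with RLE and 7096 with upper-quartile factors, 6277 without a filter, 6758 with the 1 CPM filter, 6418 over protein-coding genes, 5092 at adjusted p under 0.01, 5277 and 5292 with limma-trend on TPM with a pseudocount of 1 and 0.1 (4471 and 4482 shared), and between 5866 and 7109 with 1 library left out. After removal of the GC and length trend, 7657 were called. An absolute log2 fold change above 1 left 1002 genes, 494 higher and 508 lower, by its own construction. The genes lower in SPI1 knockdown numbered 1752 and 1754 with limma-trend on TPM with a pseudocount of 1 and 0.1, against 3580. Those fits apply no TMM factors, which lay between 1.022 and 1.032 in the knockdown libraries and between 0.967 and 0.982 in WT. Leaving them out raises every gene in the knockdown relative to WT. How much of the difference comes from this, the length correction or the test was not tested. No pairing of the cultures by replicate number was visible. Deviations of libraries with the same number correlated across genes at -0.006, -0.033 and -0.014, under the 0.1 set for pairing. These values cannot show that the cultures were handled apart. A block for the number gave 6438 genes (6399 shared). The SPI1 log2 fold change lay between -1.29 and -1.46 over its alternatives. Of the 30 lists, 13 were called by camera, 0 with an estimated correlation (7 at an unadjusted p under 0.05) and 24 by fry, which lost 1 call, added 12 and does not compare a list with other genes. CameraPR lost 1 call and added 1. Over the alternatives for named genes, 2879 comparisons kept the side of the threshold, 41 passed it newly and 49 missed it. Of comparisons called in either fit, 0 reversed direction. A change of sign in a gene called in neither fit was not counted as a reversal. On the simulated data, which held far fewer changed genes than the real comparison, 88% of genes changed 1.5-fold were recovered. A gene that was not called is not shown to be unchanged.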

Other observations

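The gene families in the next paragraphs, the value beside SPI1 and the tests on interferon-stimulated genes were chosen only after the results were seen, and so was the choice to test GC content and length, siRNA seeds and neighbouring genes, each of which was set out before its own result was seen. The splits were set at the start. The p-values of these families describe the same data that prompted them and are not independent evidence. Counts, medians and p-values of the families leave out members that had been brought out before the lists were made, which are 2 LXR targets (NR1H3 and MLXIPL), 3 dendritic cell genes (CD209, ZNF366 and FLT3), COL1A1 and 2 ZNF genes, except for the shares of ZNF genes below. The TPM fit named here is limma-trend on TPM with a pseudocount of 1. Targets of the oxysterol receptors LXR alpha and beta rose in 9 of 12 tested with 2 falling, or 8 and 2 in that TPM fit (median log2 fold change 0.45, camera adjusted p = 0.014 over the 12 added families, adjusted p = 0.153 with an estimated correlation). The cholesterol exporter ABCA1 rose from 54.7 ± 4.64 to 165 ± 13.6 CPM (SD, n = 3 each), the lipid synthesis regulator SREBF1 from 106 ± 6.88 to 168 ± 7.48 CPM and the fatty acid synthase FASN from 546 ± 69.5 to 832 ± 22.9 CPM. PLTP, a phospholipid transfer protein, fell (log2 fold change -0.80). Genes with an ABC transporter symbol had 16 of 32 higher and 4 lower, or 15 and 1 in that TPM fit (camera adjusted p = 0.00123, adjusted p = 0.115 with an estimated correlation). They were taken by symbol, ABCE1 and the ABCF genes included, whether or not they encode transporters. ABCF2-H2BK1, which shares 87.6% of its exon bases with ABCF2, is counted beside it. ABCA2 went from 103 ± 10.5 to 203 ± 6.69 CPM. Of 9 laminins 7 rose and 0 fell, or 6 and 0 in that TPM fit (adjusted p = 0.00141, adjusted p = 0.115 with an estimated correlation) and LAMC1 went from 129 ± 5.31 to 223 ± 9.31 CPM. Of 7 plexins 5 rose and 1 fell, or 4 and 0 in that TPM fit (adjusted p = 0.013, adjusted p = 0.161 with an estimated correlation), with PLXND1 at 1.05. Of 7 Wnt ligands 4 rose and 0 fell, also in that TPM fit (adjusted p = 0.0031, adjusted p = 0.115 with an estimated correlation), with WNT7B going from 16.8 ± 4.15 to 53.6 ± 2.48 CPM. Of 19 collagens 10 rose and 4 fell, or 9 and 4 in that TPM fit (adjusted p = 0.0349, adjusted p = 0.259 with an estimated correlation), with COL6A1 at 1.70 and COL9A2 at -1.01.

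Sialic acid receptors of the SIGLEC family fell in 7 of 8 with 0 rising, or 6 and 0 in that TPM fit (adjusted p = 1.78e-05, adjusted p = 0.0911 with an estimated correlation). SIGLEC1, the macrophage receptor sialoadhesin and itself interferon-inducible, went from 313 ± 14.3 to 91 ± 6.27 CPM. Dendritic cell genes fell in 6 of 10 and the lipid antigen presenter CD1D rose, or 4 and 1 in that TPM fit (adjusted p = 0.0227, adjusted p = 0.151 with an estimated correlation). Cytosolic aminoacyl-tRNA synthetases fell in 12 of 18 with 0 rising (median -0.26, adjusted p = 4.89e-04, adjusted p = 0.151 with an estimated correlation), and in that TPM fit there were 8 lower and 3 higher with a median of -0.13, and 11 and 1 with upper-quartile factors. WARS1, also induced by interferon, went from 638 ± 33.3 to 211 ± 5.96 CPM, and SARS1 had a log2 fold change of -0.62. Mitochondrial ribosomal proteins rose in 20 of 78 and fell in 4, or 36 and 1 in that TPM fit (adjusted p = 0.023, adjusted p = 0.521 with an estimated correlation), and RNA polymerase subunits rose in 15 of 34 and fell in 6, or 13 and 2 in that TPM fit (adjusted p = 0.141). Of all 13180 tested protein-coding genes, 3041 were higher and 3216 lower. Zinc finger genes with a ZNF symbol were called less often than other protein-coding genes, 145 of 459 (31.6%) against 6112 of 12721 (48%). The two-sided Fisher exact p was 2.53e-12 across genes, which are not independent. Other protein-coding genes at the expression levels of the ZNF genes were called in 46.8% of cases. Low shares were not particular to ZNF genes. Called were 30.8% of the mitochondrial ribosomal proteins, 10 of 42 oxidative phosphorylation genes and 11 of 54 cytosolic ribosomal proteins. The medians of all 12 families kept their sign with RLE and upper-quartile factors and in that TPM fit. Upstream of SPI1, the antisense gene SLC39A13-AS1 (chromosome 11, 47383148 to 47409190, minus strand), which ends 4572 bases from the start of SPI1, went from 9.86 ± 0.266 to 2.88 ± 0.271 CPM (log2 fold change -1.78, adjusted p = 3.58e-09).

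The breadth of the change, 6957 genes, was weighed against technical sources. With 10 splits of the 6 libraries a share under 0.05 cannot be reached, and the real split, 1 of the 10, gave 6957 genes while the highest of the other splits gave 0 by edgeR (between 109 and 276 at an unadjusted p under 0.05). Removal of each library's trend with GC content and transcript length left 91.2% of the called genes called with the same sign, which argues against that trend as the main source. For siRNA seeds, the trend of log2 fold change with 3' UTR length and GC content was removed first. None of the 1644 tested 7-base words of the SPI1 transcript then lowered the median of genes carrying it in the 3' UTR by 0.1. The most negative shift was -0.065 (SE 0.013), for a word that 402 genes carry. Words carried by very few genes were not tested, and the spread for rarer words was not estimated. For words at least as common as that one, the values argue against a shared seed effect of that size from a single siRNA guide strand. By difference of means over its standard error (z), the SPI1 word AACAACT ranked 2 of 16167 words (z = -3.88, median shift -0.039). The word ranked 1, ACAACTA (z = -4.11), is absent from the SPI1 transcript but overlaps AACAACT. Smaller or pooled seed effects, seeds that few genes carry, the passenger strand, transfection itself and the loss of PU.1 stay open. The design does not separate them.

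Neighbouring protein-coding genes changed together, with log2 fold changes correlated at 0.106 over 7233 pairs at least 5000 bases apart, across genes that are not independent, against a highest value of 0.035 in 1000 shuffles (p = 0.001, the smallest they can give). Pairs at that distance share no exons, and the value lies above the shuffles, which argues against overlapping reads as the whole source. The correlation was 0.009 for genes 20 places apart (highest shuffle 0.035), which argues against gains or losses of long segments, and 0.088 after the trend with GC content, length and expression was removed (highest shuffle 0.04). By distance the correlation was 0.142 at 5000 to 50000 bases and 0.077 at 50000 bases or more. At 5000 bases or more it was 0.085 once pairs whose symbols share their first 3 letters were left out (highest shuffle 0.035). Related genes side by side may therefore hold part of the value. A candidate explanation is regulation shared by nearby genes, a hypothesis that came from these data and was not itself tested. Transcription running on from a changed gene into the next was not tested.

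Interferon-stimulated genes were lower in the knockdown by a mean log2 fold change of -1.11, a value already seen when the test was written, and their mean relative to all libraries lay between -0.635 and -0.471 in the knockdown libraries and between 0.52 and 0.604 in WT. An interferon response to the siRNA in the knockdown alone would give the opposite order. At least 44 of the 45 members stayed lower whichever library was left out, so no single library carried the fall. An interferon response in the WT cultures may contribute, since type I and III interferon genes held between 23 and 26 expected counts in each WT library and between 6 and 13 in each knockdown library, mainly IFNB1 and IFNL1. Less interferon made by cells with less PU.1 would look the same, and whether the WT cells were transfected, which could also raise interferon, is not known.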
